A study of Mus musculus with 2 samples.

How the data were processed

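Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on the 4th ventricle choroid plexus, the tissue that secretes cerebrospinal fluid into the hindbrain ventricle, of wild-type CD-1 mouse embryos at embryonic day 18.5. The series holds 2 libraries: 1 made with an antibody against Meis1, a homeodomain transcription factor, and 1 input library made from DNA that was not immunoprecipitated. Samples were grouped by the antibody label. Each group has 1 library, so no difference between them has a replicate check, and every interval and p-value below covers counting error of the reads of these 2 libraries only. Reads copied by PCR are not independent molecules.

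Reads were aligned with Bowtie 1.2.3 to the mm9 mouse genome, per the submitters' processing notes. The alignment options and filters, the number of embryos behind each library and any peak calling are not given in the sources used here. The authors deposited, for each library, a list of read positions extended to 300 bp with a whole number beside each position. That number was read as the count of aligned reads at that position and strand, since 9.66% of the ChIP positions and 1.67% of the input positions carried a number above 1, while 1 position of the input list and 0 of the ChIP list were listed again. No header states this meaning. Starts in the deposited lists were taken to be counted from 0, which no header states, and positions are given here counted from 1, in mm9; another convention would move them by 1 bp. The only gene table used here belongs to another assembly (GRCm38.p6) and was used for gene names, for the chromosome a gene lies on and for the number of protein-coding genes per chromosome, never for positions.

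Everything after the read positions was computed here with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9. Chromosomes 1 to 19, X and Y were used, and 1 read was kept per position and strand, which left 12159789 ChIP and 38983036 input positions. The fragment length was taken from the strand cross-correlation of the ChIP library between 80 and 500 bp (192 bp) after a running mean over 5 bp, and each read was moved by 96 bp towards its 3′ end. ChIP reads were counted in windows of 200 bp at steps of 50 bp. Each window was tested with a one-sided Poisson test against the highest of 4 expected rates: the genome mean and the input reads in the surrounding 1 kb, 5 kb and 10 kb, scaled by 0.312, the ratio of retained reads. Adjusted p-values were computed with the Benjamini-Hochberg method over all windows with at least 1 ChIP read. Windows with an adjusted p under 0.01 and at least 3-fold over the expected rate were merged when within 200 bp and are called enriched regions. Windows in 1 kb bins with over 10 times the median input (16 reads) were left out. Fold is the ChIP count of the best window over its expected count, with the exact Poisson 95% interval of the ChIP count; the error of the expected count is not in it. The best window was chosen on the same reads, so folds of weak regions are biased upwards. Mappable length is the number of 1 kb bins with at least 1 input read, 2393 Mb in all.

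The background from read sampling was measured by drawing as many reads from the input library as the ChIP library holds. These reads were tested against the remaining input reads, with p-values adjusted within the draw. A further limit, chosen after seeing the data, was the unadjusted p that windows of the ChIP regions had to reach. The window test was tested on simulated data, in which sites of known fold were planted on a random part of the input. With 20000 planted sites, 1.2% of the 3-fold, 8.98% of the 5-fold, 65.2% of the 10-fold and 99.9% of the 30-fold sites were found, and 233 of the 8914 regions called lay away from a planted site. With 200 planted sites, 0, 0, 16 and 50 of the 50 sites of each of those folds were found, and 13 of the 79 regions called lay away from a planted site. Regions much below 10-fold are therefore largely missed at this depth.

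The regions named in the text were chosen by a rule fixed before the data were examined: the 15 regions with the lowest p and the 10 with the largest fold among those with at least 20 ChIP reads in the best window. The comparisons fixed at the same time that need gene positions or genome sequence in mm9 were not run: binding at Wnt5a, the ChIP to input ratio at its promoter, the promoter share of regions, the MEIS motif at regions and the 14 gene lists, together with the nearest gene of each named region. No mm9 annotation or sequence was used here. Alternatives changed the treatment of repeated reads, the thresholds, the window size, the scaling, the input depth, the filter on high input, the local background, the shift and the number of ChIP reads. Correlations across chromosomes are given with Pearson's r and Spearman's rho and two-sided permutation p-values from 100000 permutations, with Benjamini-Hochberg adjustment over the 8 coefficients computed.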

Results

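Meis1 occupancy was profiled in the choroid plexus of the 4th ventricle of E18.5 mouse embryos, with the stated aim of examining whether Meis1 could bind Wnt5a, a gene for a secreted Wnt ligand. The ChIP library held 13487150 aligned reads at 12163261 positions. The input library was about 3 times deeper, with 39864572 reads at 38996157 positions. Repeated reads at a position made up 9.82% of the ChIP reads and 2.18% of the input reads. Mitochondrial reads were rare, at 0.0318% of the ChIP reads and 0.0729% of the input reads. Each library stands alone, without a replicate.

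The first comparison asked whether the ChIP library held localised signal that the input lacked. In the ChIP library, reads on opposite strands were offset by a fragment length of 192 bp, where the strand cross-correlation was 2.94 times its value at long distances. The fragment-length maximum stood above the read-length maximum at 50 bp, with a relative strand coefficient of 1.33. The smoothed correlation of the input library was highest at the shortest distance searched, 80 bp, where its relative strand coefficient was 0.726. With repeated reads kept, the correlation was computed from 80 bp upwards only, in steps of 4 bp. Within that range both libraries had their highest correlation at 176 bp, at 5.84 times the long-distance value in ChIP and 5.13 times in input. The contrast in the place of this maximum therefore holds only with each position counted once. The read-length maximum was not computed with repeated reads kept, so the relative strand coefficients were not compared there.

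**Figure D1:**
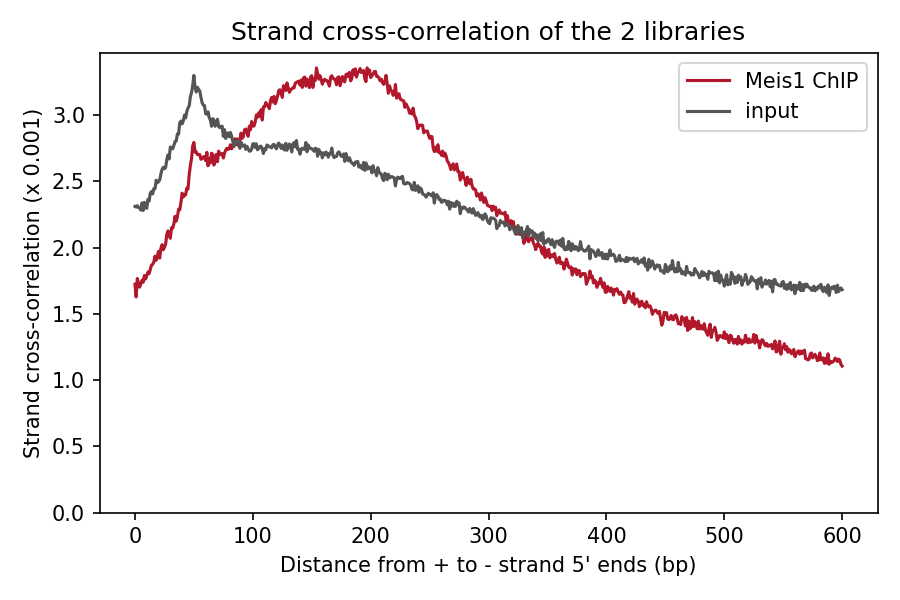
Strand cross-correlation (vertical axis, in units of 0.001) against the distance in bp between 5′ ends on the + and − strands, for the Meis1 ChIP library (red) and the input library (grey), 1 read per position. The ChIP curve has a broad maximum near 192 bp, while the input curve is highest at the read-length maximum of 50 bp.

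A total of 25916 regions were enriched in the Meis1 ChIP library over input. They had a median width of 300 bp and covered 9.06 Mb, or 0.379% of the mappable genome. The median fold over the expected rate was 8.01 (interquartile range 6.93 to 10.7). Among them, 7451 regions (28.8%) were at least 10-fold enriched, 1300 (5.02%) at least 20-fold and 63 at least 50-fold. The regions held 3.97% of the ChIP reads (exact binomial 95% interval 3.96 to 3.99) and 0.545% of the input reads (0.542 to 0.547), a 7.30-fold difference. Because the regions were chosen on these same ChIP reads, a higher share in ChIP was built in, and the intervals leave out that choice. The number of regions moved by over 1.5 times under 7 alternatives, from 5330 with a random 25% of the ChIP reads to 42633 with repeated reads kept.

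The background from read sampling was counted in the same way on input reads alone. Tested reads and background reads came from the same input library and share its local biases. Such draws cannot show non-specific pull-down or amplification differences between the ChIP and input libraries. The series has no library made with a control antibody to measure these. At the unadjusted p that windows of the ChIP regions had to reach (3.6e-05, Poisson test), 6 random draws of input reads gave 763 to 839 regions, or 2.94 to 3.24% of the ChIP count. Of these, 0 to 5 per draw were at least 10-fold and 0 were at least 20-fold. With p-values adjusted within the input draw, which sets a much stricter limit, the first draw gave 16 regions, of which 12 overlapped a region of the ChIP library, and the 5 further draws gave 8 to 14. Input reads tested against the ChIP library as background, adjusted in the same way, gave 10 regions. The test compares the reads of 2 libraries and not of conditions. Leaving out the regions also called in the first input draw at its stricter limit, and a stretch of chromosome 11 with an unusual read pattern, left 25890 regions. At the unadjusted p of 3.6e-05 (Poisson test), 33 to 47 of the input regions per draw overlapped a region of the ChIP library, and these were not left out as a set.

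To measure the enrichment on ChIP reads that had not been used to find the regions, the ChIP reads were split at random into equal parts. The input reads were not split. The expected rate thus came from input reads that also helped to choose the regions, which can raise the folds in both parts. The first part gave 12531 regions, with a median of 12.1-fold in the reads that defined them. In the reads of the other part the same regions had a median of 7.46-fold, and 86.9% of them were at least 2-fold over the expected rate. Among random places drawn in proportion to input reads, 12.6% reached 2-fold. Mean ChIP signal in the reads of the other part was 9.29 times higher within 100 bp of the summit than 1500 to 2000 bp away. Input reads at the same summits were 1.29 times their level in those flanks. Of the regions called on all reads, 24.7% were called in both parts; this share was 74.4% for regions of at least 10-fold and 4.70% for weaker ones.

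**Figure D2:**
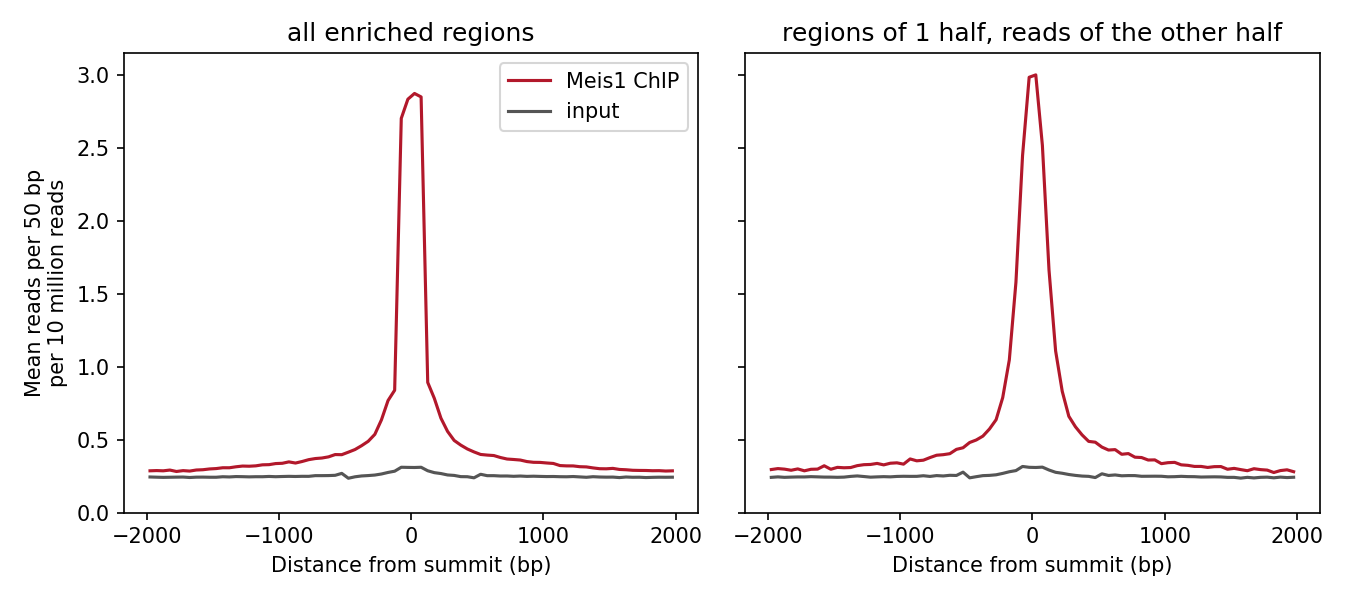
Mean number of reads per 50 bp, scaled to the same number of reads per library, against the distance in bp from the region summit, for the Meis1 ChIP library (red) and input (grey). Left, all 25916 regions with all ChIP reads, where the summit window was chosen on the plotted reads; right, the 12531 regions called in a random part of the ChIP reads, plotted with the other part, where the ChIP signal at the summit is 9.29 times that of the flanks.

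The strongest regions stood far above input. The rule for named regions gave 17 regions, 8 of them by both lowest p and largest fold, and 5 of them on chromosome 11. In 16 of the 17, the best 200 bp window held 88 to 120 ChIP positions against 2 to 8 input positions, and folds ranged from 63.6 to 96.4. These 16 were 500 to 1500 bp wide, against a median of 300 bp over all regions. Several of these folds moved by over 1.5 times with other settings, by factors of 0.558 to 1.97 over the 16 regions. With windows of 400 bp the fold of the chromosome 8 region was 44.5 and that of the chromosome 16 region 37.1, with reads not moved that of the chromosome 7 region was 52.7, and with repeated reads kept that of the chromosome 11 region at 18911051 was 179. The region with the lowest p lay on chromosome 7 (123429551 to 123431050, mm9, as all positions here), with 120 ChIP reads against 1.43 expected (84.0-fold, exact Poisson 95% interval 69.6 to 100.4; Benjamini-Hochberg adjusted p = 3.7e-174, Poisson test). The largest fold was on chromosome 12 (70472501 to 70473250), at 96.4-fold (78.3 to 117.5). Chromosome 11 held regions at 86922251 to 86923000 (85.5-fold, 70.4 to 102.9), at 120093801 to 120094450 (89.6-fold, 73.6 to 108.1) and at 5161051 to 5162100 (79.8-fold, 65.2 to 96.6). Other regions lay on chromosome 9 at 61218001 to 61218700 (76.5-fold) and 32959501 to 32960300 (83.0-fold), and on chromosome 16 at 22428751 to 22429350 (63.6-fold). Chromosome 2 had a region at 34227851 to 34229000 (67.0-fold), chromosome 1 at 45851651 to 45852400 (82.4-fold) and chromosome 19 at 53495401 to 53496050 (80.9-fold). The list was completed by regions on chromosome 8 at 73796151 to 73796650 (79.7-fold), chromosome 13 at 91600451 to 91601100 (70.4-fold) and chromosome 5 at 128354651 to 128355300 (80.1-fold). Regions with neighbouring folds have overlapping intervals, so their order is not resolved by the counts. The interval of the chromosome 16 region (52.7 to 76.1) lay below that of the chromosome 12 region, but leaves out the error of the expected count. With the genome mean and 10 kb of input only, their folds were 94.0 and 96.4. With input thinned to the number of ChIP reads they were 82.6 and 81.7, so their order is not resolved either.

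The remaining named regions differed in their read pattern. Chromosome 11 also held regions at 18915951 to 18916600 (90.6-fold, 74.6 to 108.9) and at 18911051 to 18911600 (91.0-fold, 74.1 to 110.5). Their − strand reads lay only 58 and 45.5 bp downstream of the + strand reads, near the read length of 51 bp inferred from the cross-correlation, whereas the offset was between 155 and 230.5 bp in 14 of the named regions. The region on chromosome 9 at 35112901 to 35113250 had 264 ChIP positions but also 291 input positions in the same window, and an offset of 42 bp. With 1 read kept per position and strand, a 200 bp window limits how high such counts can go. The folds of this region are therefore not plain ratios of reads, and it was not called with repeated reads kept. Its fold of 8.64 (7.63 to 9.74) is over the 30.6 reads expected from the surrounding input, while over the scaled input of that window itself (90.8 reads) it was 2.91. With the genome mean and 10 kb of input only, the fold was 65.7. It lies at the edge of a 1 kb bin with high input. Across all 7451 regions of at least 10-fold, the median offset was 168 bp (interquartile range 134 to 201). In reads not used for calling, regions of at least 20-fold had a median offset of 172.5 bp and 98.2% of them a positive one.

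**Figure D3:**
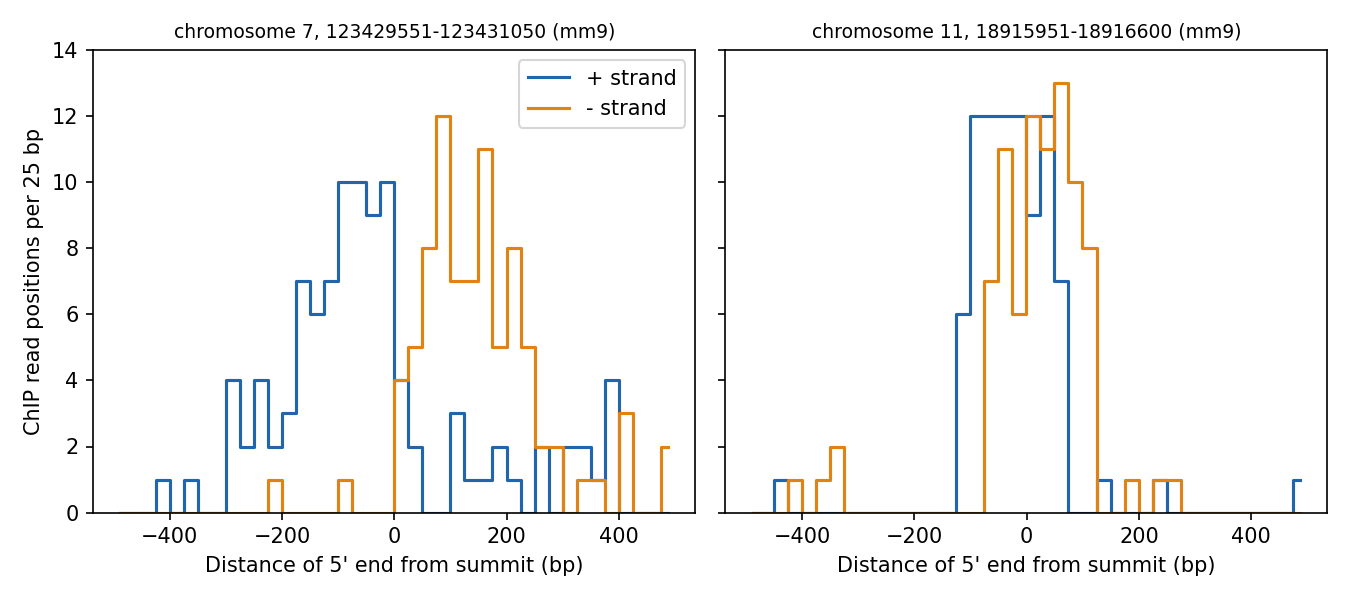
Number of ChIP read positions per 25 bp (vertical axis) by distance in bp of the read's 5′ end from the summit, on the + strand (blue) and − strand (orange). On the left, the chromosome 7 region has strands 193.5 bp apart with sloping flanks; on the right, the chromosome 11 region at 18915951 to 18916600 has overlapping strands 58 bp apart with steep edges.

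Chromosome 14, which carries Wnt5a in the RefSeq gene table, held 1057 enriched regions (4.08% of all), 321 of them at least 10-fold, with a median of 8.10-fold. This count ranged from 217 with a random 25% of the ChIP reads to 1730 with repeated reads kept. Which of them belong to Wnt5a was not analysed here, because its position in mm9 was not among the sources used. Enriched regions were most frequent between 20 and 30 Mb (154 regions), 60 and 70 Mb (143) and 70 and 80 Mb (135). They were fewest below 10 Mb (24 regions) and between 90 and 100 Mb (31) and 80 and 90 Mb (33). These are raw counts per block. Mappable length was not measured by block, so the order of the blocks may reflect it. The region with the lowest p between 20 and 30 Mb was at 25690701 to 25691350, with 104 ChIP reads against 2.31 expected (45.1-fold, exact Poisson 95% interval 36.8 to 54.6). Between 40 and 50 Mb it was at 47630701 to 47631350 (43.5-fold, 32.7 to 56.8), and between 50 and 60 Mb at 55614351 to 55614900 (48.2-fold, 37.7 to 60.8), the largest fold of the chromosome. Between 60 and 70 Mb it was at 60883701 to 60884300 (45.4-fold, 35.3 to 57.6) and between 70 and 80 Mb at 73269001 to 73269700 (43.3-fold, 32.5 to 56.5). Between 30 and 40 Mb the region at 32019651 to 32020200 reached 24.5-fold (17.1 to 33.9). The region at 104735951 to 104736450 (36.4-fold, 25.6 to 50.2) had a strand offset of 45.5 bp, like the unusual regions of chromosome 11.

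Enriched regions were spread over all chromosomes and tended to be denser on those rich in genes. Chromosome 11 had 16.8 regions per mappable Mb and chromosome 19 had 14.6, against 8.81 on chromosome 1, the lowest of the autosomes. The order was not strict: chromosome 7, with the most genes per mappable Mb of chromosomes 1 to 19 and X (16.1), had 13.0 regions. Chromosome 9, with 10.3 genes, had 13.4. Across chromosomes 1 to 19 and X, the density of regions followed that of protein-coding genes (Pearson's r = 0.713, permutation p = 0.00034, adjusted p = 0.00039; Spearman's rho = 0.886, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 2.7e-05). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.688 (permutation p = 0.0011). Read depth differed between chromosomes as well. Input had 18.1 positions per mappable kb on chromosome 11 and 17.1 on chromosome 19, against 16.1 on chromosome 1 and 10.7 on chromosome X. Depth was not matched between the autosomes, so gene density and read depth were not separated here. Chromosomes of a single pair of libraries are not independent replicates.

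Chromosome X held far fewer regions than the autosomes. It had 415 regions, or 3.05 per mappable Mb (exact Poisson 95% interval 2.76 to 3.35), against 11.3 on the autosomes, a 3.71-fold difference (3.37 to 4.10). Read depth on chromosome X was 0.644 of that on the autosomes in input and 0.616 in ChIP. Autosomal reads of both libraries were then thinned by the input ratio of 0.644, called matched depth below. This left ChIP depth slightly lower on chromosome X than on the autosomes. The densities were then 3.51 (3.20 to 3.84) on chromosome X and 7.04 on the autosomes per mappable Mb, a 2.01-fold difference (1.84 to 2.20). The ratio of chromosome X to the autosomes was 0.269 over all regions and 0.151 among regions called in both parts of the ChIP reads. Chromosome Y, with 1.31 mappable Mb, had 1 region.

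**Figure D4:**
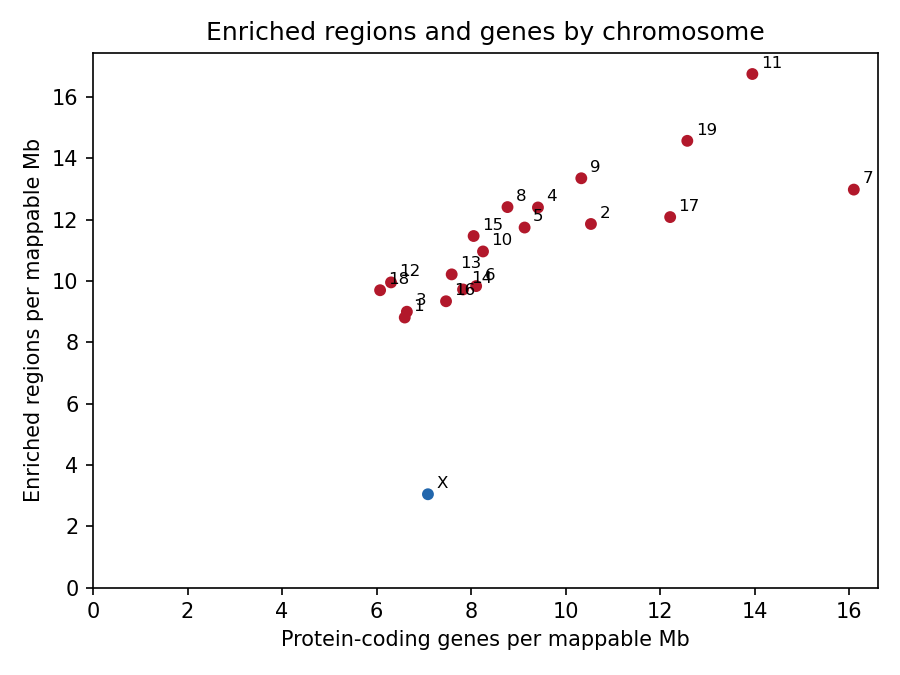
Enriched regions per mappable Mb (vertical axis) against protein-coding genes per mappable Mb (horizontal axis) for chromosomes 1 to 19 (red) and X (blue), 1 point per chromosome, with both axes starting at 0. Region density rises with gene density (Pearson's r = 0.713), and chromosome X lies at 3.05 regions per Mb, below all the autosomes.

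Enriched regions lay closer together than random placement would put them. Another region was found within 10 kb of 39.5% of the regions, against at most 21.6% in 20 random placements in proportion to input reads. The share fell with the number of regions, to 25.5% with a random part of 50% of the ChIP reads (at most 11.8% in 20 random placements of as many regions), 16.3% among regions called in both parts (at most 6.38%) and 14.6% with a random 25% of the reads (at most 5.55%). After regions within 1 kb had been merged, 32.9% of the 24517 merged regions had a neighbour at 1 to 10 kb. The highest value in 100 random placements of these was 18.7% in proportion to input reads and 17.8% in uniform placements over mappable bins. The densest blocks of 100 kb held 14 regions each and lay on chromosome 19 (22700001 to 22800000), chromosome 3 (97800001 to 97900000), chromosome 4 (153800001 to 153900000) and chromosome 2 (30500001 to 30600000). The highest fold in these blocks was 49.4, 40.4, 34.3 and 25.2, respectively.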

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

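The tests on chromosome X and on the chromosome 11 stretch were chosen only after these patterns were seen in the data, and those on gene number and on the stretch also after the values they use were seen. For read depth on chromosome X and for repeated reads, the bounds were set before the test was run.

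Reads in the 160 bins of 1 kb left out for high input stand out because they lie outside the main measurement. The ChIP library exceeded the input there only with each position counted once. Counting each position and strand once, the ratio of ChIP to scaled input was 1.44 (exact binomial 95% interval 1.42 to 1.46), and counting all reads it was 0.931. Repeated reads were frequent in these bins, with 252829 input reads at 59648 positions and 79646 ChIP reads at 26724. Counting each position once thus removed a larger share of the input reads than of the ChIP reads, which raises the first ratio. The 1.44 is therefore no measure of an excess of ChIP reads, and its interval leaves out this effect. No group has enough samples for a test of outlying samples, and no contrast was measured in more than 1 tissue or age.

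In a stretch of chromosome 11 (18783801 to 18919250, 135 kb) 14 enriched regions lay less than 50 kb apart, and all 7 of those of at least 20-fold (24.5 to 91.0-fold) had + and − strand reads offset by less than 75 bp, against 14 of the 1293 other regions of at least 20-fold. The offset itself (median 48 bp) tests nothing, since the stretch was noticed by it, but a short offset does not fix how far reads spread: the 14 others had a median span of 508 bp (71.2 to 705 bp). Sonicated fragments around a bound site are argued against by the highest span in the stretch, 342 bp, below the 5th percentile of the other strong regions (390 bp), and extra copies of the sequence in CD-1 mice by input at the summits, 1.18 times the rate of the surrounding 10 kb (0.793 to 1.70). DNA that covers only a short sequence, such as DNA copied from a spliced transcript or an amplified product, may account for these reads. Their median span was 145 bp. Fragments that all end at the same few positions are argued against by the spread of 5′ ends. With each position counted once, the 7 regions had 15 to 84 + strand and 16 to 84 − strand positions within 400 bp of the summit. The gene for Meis1 itself is also on chromosome 11, but whether it occupies this stretch was not analysed here, so the source stays open.

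Chromosome X had 3.71 times fewer regions per mappable Mb than the autosomes. Lower read depth, as measured in input, is not the whole cause, since a 2.01-fold difference (1.84 to 2.20) was left at matched depth. The test of gene number set before the result was seen, regions per gene at matched depth, decided nothing (0.495 on chromosome X, 0.451 to 0.541, against 0.499 on chromosome 7, the lowest autosome), and it was then replaced. In the test that replaced it, chromosomes 1, 3, 12 and 18, with fewer protein-coding genes per mappable Mb than chromosome X, had at least 5.46 regions per Mb at matched depth, above the upper bound of 3.84 for chromosome X, which argues against gene number as the whole cause. Base composition, the sex of the embryos and a difference in chromatin between chromosome X and the autosomes stay open, and the design has no group with which to test a biological explanation.

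On chromosomes 1 to 19, X and Y, repeated reads made up 9.81% of the ChIP reads and 2.14% of the input reads, 4.59 times as many. Pile-up of fragments at bound sites is not the cause, because outside the enriched regions, with 2 kb added on each side, the ChIP library still had 9.62% repeated reads against 2.04% in input, 4.72 times as many, whereas inside the regions the shares were 13.4% and 13.7%. Chance collisions of independent reads would give 0.141% at this depth. Amplification of a smaller amount of immunoprecipitated DNA, which could raise repeats everywhere, stays open and was not tested; no biological explanation was tested.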

How the results depend on the processing

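Chosen after seeing the data were the random 25% and 75% of the reads, the regions called in both parts, merging within 1 kb, the input background at the p of the ChIP regions, the thinning to the depth of chromosome X (set before its own result was seen) and the set without the chromosome 11 stretch and regions called in input. The number of enriched regions (25916) moved by over 1.5 times under 7 alternatives. Keeping repeated reads gave 42633 regions, an adjusted p under 0.0001 gave 12502 and one under 0.05 gave 41700. Random parts of 50% of the ChIP reads gave 12531 and 12527 regions, a random 25% gave 5330, and 6412 regions were called in both 50% parts. With a random 75% there were 19325 regions, so the count was still rising at the full depth and is limited by the number of reads. Under the 11 remaining alternatives, this one included, it stayed between 17833 (reads not moved) and 32892 (no local background from 1 kb and 5 kb of input). Not moving the reads kept 60.7% of the regions, and windows of 400 bp kept 86.2%. The background count in input (16) became 4 at an adjusted p under 0.0001 and 6 at a minimum of 5-fold, and was 799 at the unadjusted p that the ChIP regions reached, since adjustment within the input draw sets a stricter limit. The cross-correlation of the ChIP library over its long-distance value rose from 2.94 to 5.84 with repeated reads kept, and from 1.70 to 5.13 in input; the cause was not tested. The ratio of region density on chromosome X to that on the autosomes ranged from 0.151 (regions called in both 50% parts) to 0.498 (matched depth) and was 0.269 as reported. All 17 named regions were called under each alternative other than the thinning to the depth of chromosome X, where this was not examined, except that the chromosome 9 region with high input was lost with repeated reads kept and with reads not moved, and that 2 named regions belong to the chromosome 11 stretch left out in another. The fold of the chromosome 9 region rose from 8.64 to 65.7 without the local background from 1 kb and 5 kb of input, and the folds of the other 16 moved by factors of 0.558 to 1.97. The count on chromosome 14 moved by over 1.5 times under 7 alternatives (217 to 1730). The share of regions with a neighbour within 10 kb moved beyond its binomial interval under 13 alternatives (14.6 to 47.2%), and was above its own 20 random placements under each of these and the other alternatives, the thinning to the depth of chromosome X not examined. No paired analysis was possible because each group has 1 library, and none could be left out. Alternatives for binding at Wnt5a, the promoter share, the MEIS motif and the gene lists were not run.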

Other observations

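All the values here were chosen after the data had been seen, except the bound for merged regions, which was set before its result. After merging within 1 kb, the share of regions with a neighbour at 1 to 10 kb was 1.76 times the highest of 100 placements in proportion to input reads and 1.86 times that of uniform placements; the bound set to exclude signal split into several regions was 2 times, so that stays open. With each position counted once, input was slightly concentrated at the enriched regions. The median input at a summit was 1.18 times the rate of the surrounding 10 kb, and 3204 regions (12.4%) had at least 2 times that rate and 416 (1.61%) at least 3 times. These values include the counting error of few input reads per window. They leave out repeated reads, which, as given above, made up 13.7% of the input reads inside the regions and 2.04% outside them. The cause of that difference within input was not tested. Outside the chromosome 11 stretch, among regions of at least 20-fold with a short strand offset, the region of largest fold lay on chromosome 17 (4626051 to 4626800). It had 85 ChIP reads and 0 input reads in its best window (71.7-fold over the expected rate, exact Poisson 95% interval 57.3 to 88.7) and an offset of 54 bp. Another, on chromosome 1 (12634651 to 12635100), was 27.3-fold enriched (18.3 to 39.3) with an offset of 52.5 bp and a read span of 196 bp.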
